A study of Mus musculus with 4 samples.

How the data were processed

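Footpad RNA of 2 wild-type and 2 Tabby mouse samples at postnatal day 5 was measured on 2-colour oligonucleotide arrays with probes of 60 bases. Per the labels, Cy3 carried the footpad RNA and Cy5 a common reference made of RNA from cultured mouse cell lines and embryonic stem cells, on every array and with no dye swap, so a dye effect of a probe is the same in both genotypes and drops out of the comparison only if it does not depend on signal. Per the file headers, the 4 arrays lie on 1 slide and were read in 1 scan, so slide and scan could not be tested as batches. The array's position on the slide and genotype cannot be told apart.

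The deposited spot intensities, mean and local background per channel, were made with Agilent Feature Extraction 9.5.1.1, per the file headers, and the submitters' processing notes name the same software. Per the file headers, the deposited processed intensity is background subtracted with a spatial detrend and dye normalized by linear and LOWESS factors, and the deposited log10 ratio is that of processed Cy5 over Cy3. The authors' series value table holds log10 values for 25164 probes. Differences between its columns follow the scanner's log ratio turned to footpad over reference, and its column medians are 2.6157 and 2.6243 for wild type and 2.61125 and 2.6136 for Tabby. How its probes were chosen and how its level was centred are not given in the sources used here, and it served only as an alternative.

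The files do not pair probe identifiers with gene names. Of 42006 probes, 0 had a gene name other than the probe identifier, 0 had a description and 0 had a coordinate, and 0 identifiers matched the gene table used here. The tests were therefore made per probe. Eda, the gene affected in Tabby, and the 26 gene lists fixed before the data were examined could not be tested, and no gene was named from a sequence. The rule for named items, fixed beforehand, took the 12 largest falls and 12 largest rises past the threshold with both Tabby values on the same side of both wild-type values. With no gene names, it was held to the first 2 in each direction.

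Background was corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3, which draws dim probes towards a ratio of 1 and understates their changes. Log2 ratios of Cy3 over Cy5 were normalized within each array by loess, with the 1417 control spots given no weight and then left out. Spots with outlier flags (7 and 2 on the wild-type arrays, 7 and 6 on the Tabby arrays) were left out, and repeated spots of a probe were averaged, which concerned 7 probes. A probe was tested if Cy3 was well above background on both arrays of at least 1 genotype. That removed 13702 probes, 2 more had no value left in a genotype, and 28302 were tested.

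Genotypes were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The fit had a prior of 4.10 degrees of freedom and a median standard error of 0.06 on the log2 scale. At an unadjusted threshold of 0.05, 7096 probes passed, against 1415 expected by chance. With 2 samples per genotype a permutation test of a single probe cannot go below a two-sided exact share of 33.3%, so the p-values rest on the model. Adjusted p values in the text are limma's unless Fisher's exact test is named. For a probe not well above background on both arrays of 1 genotype, the change is given as a bound from the mean of, per array, the higher of the probe's signal and the lowest signal among probes well above background, in single channels after loess and between-array quantile normalization of intensity (Aquantile). Such bounds stay open to dye bias.

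The fit was tested on simulated log ratios for 28299 probes of this comparison, 200 of them changed. It recovered 58% of 1.5-fold, 82% of 2-fold, 98% of 4-fold and 100% of 8-fold changes, 50 probes each, with 4 false calls. The simulated noise was normal and independent between probes and arrays, with the replicate spreads shuffled over probes. Changes were added to log ratios after background correction. With no effect shared by probes of an array, the 4 false calls do not give the error rate of the real data. Probes were joined into groups where they share an identical run of 20 bases. Alternatives fixed before the data were examined covered background correction, normalization, use of the reference, filters, flags, the variance model, the replicate numbers, each array left out, the series table and the threshold. The counts of changes of 4-fold or more and the alternatives on array surface, GC content, shared sequence, ratio slope and centring over tested probes were chosen after seeing the data.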

Results

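RNA from the footpads of mice at postnatal day 5 was compared between wild-type animals and Tabby mutants. Tabby mice lack functional ectodysplasin A (Eda), a ligand of the tumour necrosis factor family that is needed for hair follicles, teeth and sweat glands to form, and the footpad is the main site of sweat glands in the mouse. The stated purpose of the study was to find genes that depend on Eda while sweat glands develop. The day 5 samples comprised 2 wild-type and 2 Tabby footpad RNAs, all labelled as C57BL/6. Each was labelled with Cy3 and hybridised against the same Cy5-labelled reference, a pool of RNA from cultured mouse cell lines and embryonic stem cells. The value for each probe was therefore the log2 ratio of footpad to reference signal, and the comparison was the difference of these ratios between genotypes. The wild-type samples were labelled male and the Tabby samples mixed sex, so sex and genotype differed together in every comparison. The labels do not state whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

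Of 42006 probes, the footpad channel was well above background for 27703 and 29287 on the wild-type arrays and for 28890 and 28550 on the Tabby arrays. The median Cy3 spot brightness was 99.9 and 124 on the wild-type arrays and 134 and 145 on the Tabby arrays, in scanner intensity units, against local backgrounds of 42 to 44, so both Tabby arrays were brighter in this channel than both wild-type arrays. No spot was saturated. After normalization, the log2 ratios of the wild-type arrays differed from each other with an SD of 0.123 over probes, and those of the Tabby arrays with an SD of 0.127. Arrays of different genotype differed with SDs of 0.225 to 0.250. The number of arrays, 2 per genotype, limits the precision of every value.

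Tabby footpads at day 5 had lost much of the signal of a small set of transcripts, and few transcripts had gained as much. Of 28302 probes tested, 1072 (3.79%) differed between genotypes at an adjusted p of 0.05 with limma, 498 of them higher and 574 lower in Tabby. Among large changes the directions were unequal. 42 probes fell at least 4-fold in Tabby and 1 rose at least 4-fold, and at 8-fold or more the counts were 18 and 1. Between 2-fold and 4-fold, 75 probes fell and 21 rose. Under 1.5-fold the order turned, with 412 probes higher and 356 lower, so that 768 of the 1072 calls were changes of under 1.5-fold. In each of the 1072 called probes both Tabby values lay on the same side of both wild-type values. Groups of 2 that overlap cannot pass this threshold, so this follows from the calls and adds no support to them. Such separation held for 57.2% of all tested probes, against 33.3% expected by chance for 2 against 2.

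**Figure D1:**
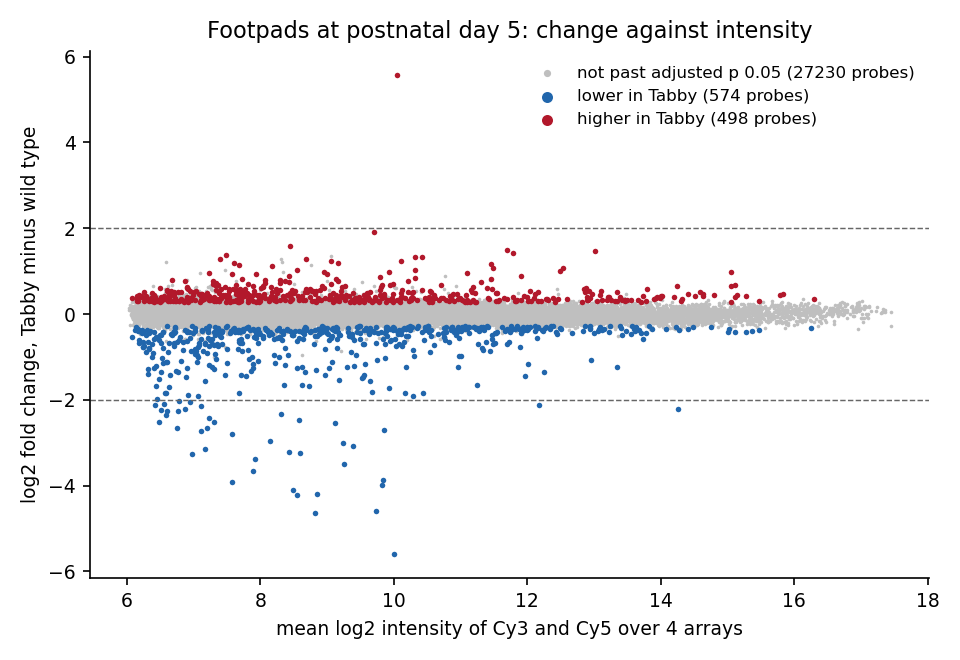
Each point is 1 of 28302 tested probes, with the mean log2 intensity of both channels over 4 arrays on the horizontal axis and the log2 fold change, Tabby minus wild type, on the vertical axis; blue points are the 574 probes called lower in Tabby, red points the 498 called higher, and dashed lines mark 4-fold changes. 42 called probes lie at or below the lower dashed line and 1 above the upper line.

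**Figure D2:**
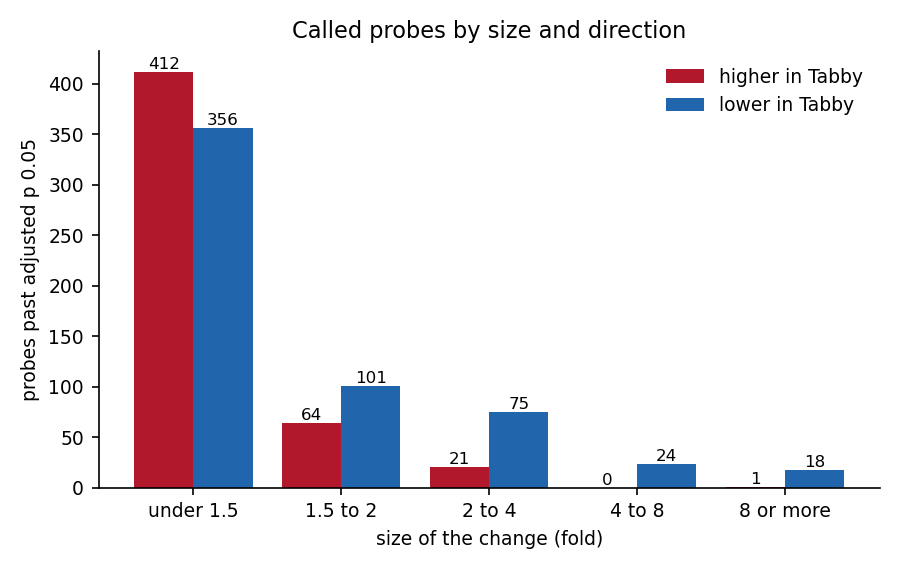
Bars count the probes called at an adjusted p of 0.05 by the size of their change (fold, horizontal axis) and its direction in Tabby. Falls outnumbered rises in every class from 1.5-fold upwards, 101 to 64 in the lowest of these and 18 to 1 in the highest.

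The counts of calls depended on single arrays and on the normalization. The 498 higher and 574 lower calls became 208 and 313 without wild-type replicate 1, 247 and 272 without Tabby replicate 1, and 116 and 248 without Tabby replicate 2, while all 42 probes lowered at least 4-fold passed the threshold whichever array was left out. The probes raised at least 4-fold numbered 5 in place of 1 without wild-type replicate 2, 2 with 1 or the other Tabby replicate left out and 4 with the scanner software's processed signals, and where signal was required in both channels on all arrays, 0 were raised and 24 lowered at least 4-fold. With each array centred on its median in place of loess, the median change over all tested probes shifted to 0.28 on the log2 scale and the split became 9548 higher and 249 lower, and with the scanner software's own processed signals it became 28 higher and 128 lower.

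Of the 42 probes lowered at least 4-fold, 40 stood above the reference in wild-type footpads, against 15484 of all 28302 tested probes. The reference signal of 9 of the 42 was not well above background on any array, so their ratios rest on a reference level that was not measured. Over all 42, the median log2 ratio of footpad to reference was 2.81 in wild type and 0.38 in Tabby, and the median change was -2.72 (median SD between replicates 0.11 in wild type and 0.09 in Tabby, n = 2 each). In wild type, 39 of the 42 stood at least 2-fold above the reference, against 4998 of all tested probes, and in Tabby 9 of the 42 did. The 42 were picked for their fall, so lower ratios in Tabby than in wild type follow from the choice. The choice also favours probes with a high ratio in wild type, since a probe with little footpad signal there cannot fall as far. The counts above the reference in wild type are partly set by this. In Tabby, 30 still lay above the reference. All 42 had adjusted p values of 0.00476 or less with limma. The Cy3 signal of 9 of the 42 was not well above background on either Tabby array, so that only a lower bound on their fall could be given. With these at their bounds, 41 of the 42 still fell at least 4-fold and the size of the median change was 2.72.

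The largest fall was that of probe Z00047655-1 (sequence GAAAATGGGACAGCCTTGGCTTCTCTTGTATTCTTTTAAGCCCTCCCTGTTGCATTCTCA). Its log2 ratio to the reference was 6.47 ± 0.11 (SD, n = 2) in wild type and 0.87 ± 0.12 (SD, n = 2) in Tabby. The change was -5.59 (SE 0.08, limma adjusted p = 7.67e-06), or 48.2-fold lower, with a 95% confidence interval of -5.80 to -5.38. The interval covers only the spread between these arrays under 1 processing. With median centring in place of loess the change was -4.86, and with Cy3 alone it was -6.68, both outside the interval. Footpad signal at this probe was well above background on all 4 arrays. A second tested probe that shares a run of 20 bases with it fell as well, with a change of -4.58.

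The second largest fall was at probe Z00050873-1 (sequence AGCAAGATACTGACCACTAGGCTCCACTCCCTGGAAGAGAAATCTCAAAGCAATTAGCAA), 25.1-fold lower in Tabby. The log2 ratio was 5.79 ± 0.06 (SD, n = 2) in wild type and 1.14 ± 0.12 (SD, n = 2) in Tabby, a change of -4.65 (SE 0.07, limma adjusted p = 7.67e-06). At Z00047655-1 the Cy5 signal, which came from the same reference RNA on every array, was also lower on the Tabby arrays, by a log2 difference of -1.47, and at Z00050873-1 that difference was -1.44. In the Cy3 channel alone the changes were -6.68 and -5.67. Why Cy5 fell was not tested, so it is open whether the ratio or Cy3 alone is nearer to the change in RNA.

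Of the probes that rose, Z00016441-1 (sequence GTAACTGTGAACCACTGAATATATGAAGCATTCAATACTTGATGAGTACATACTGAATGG) stood apart from all others. Its footpad signal was well above background on both Tabby arrays and on neither wild-type array. The log2 ratio was 1.08 ± 0.04 (SD, n = 2) in Tabby and -4.50 ± 0.32 (SD, n = 2) in wild type, where it is only an upper bound, and the limma adjusted p was 2.61e-05. By the rule for bounds, the transcript was at least 41.3-fold higher in Tabby. On both wild-type arrays the probe's own signal was the higher of the values that the rule compares, so the bound rests on it. The reference signal at this probe was well above background on all 4 arrays. The wild-type samples were male and the Tabby samples of mixed sex, which applies to this probe as to all others. The second largest rise, at Z00025066-1 (sequence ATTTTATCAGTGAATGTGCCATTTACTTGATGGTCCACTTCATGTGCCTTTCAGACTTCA), was 3.74-fold. Its log2 ratio was -0.30 ± 0.03 (SD, n = 2) in wild type and 1.60 ± 0.05 (SD, n = 2) in Tabby (change 1.90, SE 0.06, limma adjusted p = 4.45e-05).

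**Figure D3:**
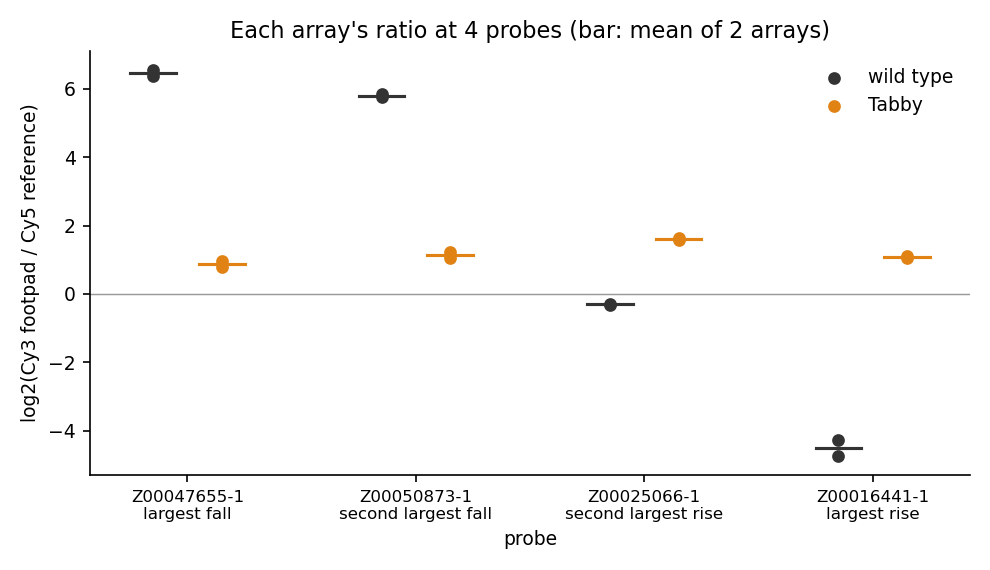
Points give the log2 ratio of Cy3 footpad to Cy5 reference signal on each array for the 2 probes with the largest falls and the 2 with the largest rises, black for wild type and orange for Tabby, and each bar is the mean of 2 arrays. At every probe the distance between genotypes, 1.90 or more, exceeds the distance between replicates; the wild-type points of Z00016441-1 are not well above background.

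Footpad signal was well above background on both wild-type arrays and on neither Tabby array for 129 probes, and 44 of these were called lower in Tabby. The converse held for 143 probes, of which 5 were called higher in Tabby. The direction of these calls largely follows from how the 2 classes are defined. Over all 28302 tested probes, 574 were called lower and 498 higher. Both the bound and the fold of the ratio reached 2-fold for 21 of the 44 called falls and 4-fold for 8, and they reached 2-fold for 2 of the 5 called rises and 4-fold for 1. Among the 27053 probes well above background on all 4 arrays, 488 were higher and 512 lower.

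The frequency of large changes differed with the ratio of footpad to reference. Of 4018 probes whose ratio, averaged over all 4 arrays, lay 2-fold to 8-fold above the reference, 44 fell at least 2-fold. Their odds of doing so were 3.67 times those of all other tested probes (95% confidence interval 2.46 to 5.42, Fisher's exact test, two-sided, adjusted p = 1.42e-09 over 5 ratio classes). Of 20104 probes within 2-fold of the reference, 52 fell as far (odds ratio 0.32, Fisher's exact test, adjusted p = 5.08e-09). Among 2804 probes 2-fold to 8-fold below it, 7 fell as far (odds ratio 0.58, Fisher's exact test, adjusted p = 0.212). Among 276 probes more than 8-fold below the reference, 5 fell at least 2-fold (odds ratio 4.60, Fisher's exact test, adjusted p = 0.00979). Among 1100 probes 8-fold or more above it, 9 fell as far, which did not pass the threshold (odds ratio 2.07, Fisher's exact test, adjusted p = 0.0606), and 5 rose at least 2-fold (odds ratio 7.30, Fisher's exact test, adjusted p = 0.00666). The test was repeated on 22088 bright probes. Their Cy3 signal, averaged over all 4 arrays, lay at least 2-fold above the lowest signals counted as well above background. Odds ratios for a fall were 3.44, 0.29, 0.64, 6.55 and 1.94 for these classes in the same order. The adjusted p values were 3.23e-08, 1.33e-08, 0.325, 0.0023 and 0.0775 (Fisher's exact test). A fall lowers this Cy3 average, so probes that fell can drop out of the bright set. The average ratio also includes the Tabby arrays, so a fall itself moves a probe to a lower class. The contrast between neighbouring classes is partly set by this split. Probes are not independent replicates, and these tests describe the tested probes of these 4 arrays.

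Probes whose reference signal was not well above background on any array more often fell at least 2-fold. Of 1441 such probes, 22 were at least 2-fold lower in Tabby, against 95 of the other 26861 (odds ratio 4.37, 95% confidence interval 2.61 to 7.03, Fisher's exact test, two-sided, p = 9.91e-08). Among the bright probes, the counts were 12 of 370 without reference signal and 98 of 22088 in all (odds ratio 8.43, Fisher's exact test, p = 9.1e-08). Calls of any size did not favour falls, with 47 higher and 48 lower among the 1441, against 451 and 526 among the others, and 1 of the 1441 rose at least 2-fold.

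The counts of calls in each direction varied over these classes and depended on the scale of the ratios. Among 1100 probes 8-fold or more above the reference, 50 were higher and 15 lower in Tabby, and among 2804 probes 2-fold to 8-fold below it, 26 were higher and 129 lower. The slopes of each array's ratios on the mean ratio were 0.978 and 0.996 for wild type and 1.01 and 1.02 for Tabby. With every array scaled to the same slope, an alternative chosen after seeing the data, the counts became 41 and 35 in the first class and 44 and 90 in the second. Over all probes of a class, the median change went from 0.03 to -0.06 in the first class and from -0.08 to -0.03 in the second, so the order of the medians turned. Among the 4018 probes 2-fold to 8-fold above the reference, 160 higher and 103 lower calls became 138 and 142 with this scaling, among the 276 probes more than 8-fold below it 0 and 15 became 3 and 10, and among the 20104 probes within 2-fold of it 262 and 312 became 301 and 318.

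Probes that share sequence gave a check within each array. Over 714 pairs of tested probes that share at least 1 run of 20 bases, the changes correlated with r = 0.963 across pairs. Pairs with large changes, such as that at -5.59 and -4.58, weigh heavily in this r. It does not show how well small changes match within pairs. In 39 pairs at least 1 probe was called, and in all 39 both probes changed with the same sign. In 22 pairs both were called. In 23 groups of such probes 2 or more members were called, and the direction was the same within each group, lower in 16 and higher in 7. The 42 probes lowered at least 4-fold belonged to 38 separate groups, which need not be 38 transcripts.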

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

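The test of sex was chosen only after the result was seen. Probe Z00016441-1 was at least 41.3-fold higher in Tabby and was well above background on 0 of the 2 wild-type arrays. A spot or reference artefact is argued against by the Cy5 signal, which differed by -0.073 on the log2 scale between genotypes where a faulty spot or uneven reference was predicted to move it by at least 1. What stays open is whether genotype or the sex of the animals gave the rise. A transcript of female animals could be absent from male wild-type footpads and present in a mixed-sex pool, and the 0 wild-type arrays with signal go with both, so sex and genotype cannot be told apart here for this probe. A gene name or samples of 1 sex would settle it.

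The excess of large falls, 42 probes at least 4-fold lower in Tabby against 1 at least 4-fold higher, was set against 2 technical explanations. If a few transcripts measured by many overlapping probes made up the list, at most 3 sequence groups were predicted to hold it, and there were 38. If uneven reference signal made the falls, Cy3 alone was predicted to call fewer than 5 of them, and it called 43 probes at least 4-fold lower, 38 of which were among the 42. Uneven reference signal is argued against. Only 1698 of the 28302 tested probes lay in a group with another tested probe, so most lists of 42 would span many groups. The prediction on groups was therefore unlikely to be met and decides little. The narrower count is that 7 of the 42 lay in a group with another tested probe. Probes on separate stretches of 1 transcript count as separate groups, so the number of transcripts behind the 38 groups is not known. Loss of transcripts of structures that fail to form without Eda is a hypothesis that may account for the falls, and it was not tested because the probes carry no gene names. The labelled difference in sex stays open, as would any difference in how tissue was taken, and neither was tested.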

How the results depend on the processing

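The tests of surface, GC content, shared sequence, ratio slope and centring over tested probes, and all counts at 4-fold, were chosen after seeing the data. Z00047655-1, Z00050873-1, Z00025066-1 and Z00016441-1 kept their direction and passed the threshold in all 82 values over the alternatives that gave one. The number lowered at least 4-fold (42) lay between 29 and 60 except for 24 where signal was required in both channels on all arrays, which removes probes that lack signal in Cy3 or Cy5 on at least 1 array and left 0 raised at least 4-fold. Membership moved more than the count. Of the 60 with processed signals 33 were among the 42, and of the 46 with series matrix values, which cover fewer probes, 22 were. 33 of the 42 were called lower under all of 5 alternatives: offset 10, no background correction, processed signals, Cy3 alone and centring over tested probes. Of all calls, 16 of the 498 higher and 110 of the 574 lower were called under all 5. The 498 higher and 574 lower calls moved much more. They became 110 and 263 with offset 10 (2 raised 4-fold), 28 and 128 with processed signals (4 raised 4-fold), 31 and 110 among 17708 probes with the series matrix values (4 raised 4-fold; 312 and 414 of the calls are in that table), and 1331 and 1429 with an intensity trend in eBayes. Median centring in place of loess gave 9548 and 249 (2 raised 4-fold), and centring over tested probes gave 2029 and 1871; both fits had infinite prior degrees of freedom. An adjusted p of 0.1 gave 1612 and 1510, requiring 1.5-fold gave 86 and 218, and no filter on dim probes, which adds tests, gave 301 higher. Except where the construction shows it, the cause was not tested. Leaving out each array gave 116 to 411 higher, 248 to 464 lower, 1 to 5 raised and 41 to 42 lowered at least 4-fold, with the lone sample assumed to vary like the other group. 83 of the higher and 212 of the lower calls passed in all 4 of these fits. Aquantile leaves ratios unchanged and so tests nothing. With the replicate numbers as a block (replicate block) the counts were 1129 and 1083. The deviations of same-numbered samples correlated with r = 0.138 over probes, and with 2 pairs the samples share only a number. Averaging all probes of a gene, and every alternative for Eda and for the gene lists, were not run because probes carry no gene names. Signal over background limits dim probes, whose changes are bounds.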

Other observations

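The test of the ratio slope was chosen only after the result was seen. 768 of the 1072 calls were changes of under 1.5-fold, and 4 technical explanations were tested for them. Array differences that reach both channels were tested in the reference channel. Over the same 26226 probes Cy5 alone gave 25 calls, 3.25% of the 769 in Cy3 alone, and 0 of the 25 were under 1.5-fold. Of the Cy3 calls, 457 were under 1.5-fold. The counts argue against differences of equal size in both channels as the source of the Cy3 calls. They do not test the 768 directly, as these are calls on ratios. Changes in Cy5 and Cy3 correlated with r = 0.572 over these probes, so differences shared in part by both channels stay open. After removing medians over 200 blocks of the array surface 637 of the 768 were still called, after removing medians of 15 GC classes 725, and after scaling ratios to the same slope 664, so these trends are argued against as the whole cause. The reference cannot show a difference in the Cy3 labelling or amount of footpad RNA, and both Tabby arrays were brighter in Cy3. Nor can it show the labelled difference in sex, or any difference in footpad dissection or RNA quality. All of these could account for part of the small changes and stay open beside genotype.

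The reference channel followed the largest falls. Among the 42 probes lowered at least 4-fold, the Cy5 signal of both Tabby arrays lay below that of both wild-type arrays for 31 (73.8%), against 20.7% of all tested probes and 16.7% by chance. The median Cy5 difference of the 42 was -0.40 on the log2 scale, the lowest was -2.96, and 9 fell by 1 or more, out of 12 such probes among all 28302. Among the 22 probes raised at least 2-fold, Cy5 was higher on both Tabby arrays than on both wild-type arrays for 14. Over 26226 probes the changes in Cy5 and Cy3 alone correlated with r = 0.572 across probes, which are not independent replicates. Whether this came from Cy3 signal read in the Cy5 channel, or from spots that lost signal in both, was not tested, and it leaves the exact size of the largest changes open.

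Large falls were counted by intensity. When the tested probes were divided by mean intensity into 5 classes of about equal size, the 3 dimmer classes held 34, 31 and 38 probes lowered at least 2-fold, and the 2 brighter classes 7 each. The mean includes the Tabby arrays, so a fall itself lowers the class of a probe. The rises of at least 2-fold numbered 0, 5, 6, 8 and 3 from the dimmest class to the brightest.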
